A study of Mus musculus with 16 samples.

How the data were processed

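Per the labels, 16 mouse heart libraries came from 4 groups of 4 animals each: wild-type (WT) or ERBB2-overexpressing (OE) hearts, taken 2 weeks after sham surgery or after myocardial infarction (MI) made by tying off the left anterior descending artery for good. Age at collection was about 3 months per the labels. RNA was isolated with a miRNeasy kit, and polyA-selected libraries were made with TruSeq chemistry, per the labels' protocols. The labels stated no sex, no sequence or species of the overexpressed ERBB2, and no cell type or promoter for it. Each title carried an RA number from 1 to 17, with 13 absent, whose meaning was not stated. Per the labels, WT sham hearts were the controls of OE sham hearts and of WT infarcted hearts, so that these 2 comparisons share 4 libraries.

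Upstream steps were those of the series design text: single 60-nt reads were trimmed with cutadapt, reads under 40 nt were dropped, and each library was subsampled to the same number of reads. That text names TopHat 2.0.10 for alignment to mm10, HTSeq-count 0.6.1p1 for counting over RefSeq genes and DESeq2 1.6.3 for testing. The submitters' processing notes name the same aligner and testing tool. The 16 per-sample columns deposited by the authors hold signal, read here as gene counts divided by 1 size factor per library. The authors' deposited table gives a log2 fold change, p-value and Benjamini-Hochberg adjusted p-value per gene for 4 comparisons, per the file headers. All log2 fold changes, adjusted p and list tests given here were computed anew from the per-sample signal unless the authors' deposited table is named.

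Groups, comparisons, most processing alternatives and the rule for naming genes were fixed before the data were examined. That plan assumed read counts and the edgeR quasi-likelihood test. The per-sample values were normalized, so limma with a trended variance on log2(value + 1) was used in its place, and the count tools became alternatives. Whole reads were recovered by dividing each column by its smallest step, and 100% of the positive values were whole multiples of that step within a tolerance of 0.001. The recovered totals, 11939093 to 17468914 reads per library, were used for CPM (counts relative to the library total), DESeq2, edgeR and voom. Values called normalized reads below are the deposited ones.

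The table held 24421 genes. Genes with a value of at least 10 in at least 4 libraries were tested, which left 14298. A model with 1 mean per group over all 16 libraries gave 5 contrasts: OE against WT in sham hearts, OE against WT in infarcted hearts, MI against sham in WT hearts, MI against sham in OE hearts, and the interaction of OE and MI, which is the MI effect in OE minus that in WT hearts. Each contrast was adjusted over all tested genes with the Benjamini-Hochberg method, and a gene passed at an adjusted p below 0.05. SE denotes the moderated standard error of a log2 fold change, and SD the spread of the 4 animals of a group. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

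Before the data were examined, 34 gene lists of up to 29 members were written down: YAP target genes, EMT genes, ERK feedback and ETS target genes, ERBB ligands and receptors, S-phase genes, G2/M and cytokinesis genes, sarcomere genes, fetal and dedifferentiation genes, calcium handling and ion channel genes, fatty acid oxidation genes, TCA cycle genes, oxidative phosphorylation genes, glycolysis genes, serine synthesis and ATF4 target genes, fibrillar matrix and fibrosis genes, basement membrane genes, actin cytoskeleton and adhesion genes, nuclear envelope and LINC complex genes, inflammatory cytokine and chemokine genes, interferon-stimulated genes, immediate-early and heat shock genes, fibroblast markers, endothelial markers, mural cell markers, macrophage markers, neutrophil markers, T and NK cell markers, B cell markers, epicardial and mesothelial markers, Schwann cell markers, adipocyte markers, atrial markers, skeletal muscle markers, erythroid markers. Of their 608 genes, 605 were found. Lists with at least 5 tested members, 33 of 34, were tested against all other genes with camera in limma at a preset inter-gene correlation of 0.01, and p was adjusted over the lists of a comparison. The same test with a correlation estimated from the residuals was run as an alternative, and no list passed it in any comparison. Erythroid markers had 3 tested members and are described by counts alone. The count of members that passed was also taken with p adjusted over the list alone. EMT denotes epithelial-to-mesenchymal transition, and the TCA and LINC names stand for the tricarboxylic acid cycle and the nucleus-to-cytoskeleton linker.

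By the rule for naming genes, 12 genes were followed in each comparison: Erbb2, Ctgf, Cyr61, Ankrd1, Vim, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1 and Postn. The 6 largest rises and 6 largest falls were added from genes that passed, had a mean of at least 5 CPM in the higher group and showed no overlap between libraries of the groups, a condition not asked of the interaction. For each list, up to 3 members with the smallest p in the direction of the test and up to 2 that passed in the other direction were eligible. Fewer are named below. Most of the eligible genes named also passed with each library left out, a choice made after the values were seen. Of the eligible genes that passed, 13 of 129 lost the call without at least 1 library in the sham comparison of OE and WT, 19 of 112 in the infarcted comparison, 41 of 63 for MI in WT hearts, 1 of 1 for MI in OE hearts and 7 of 8 for the interaction. Lung and thymus terms ended 2, 54, 48, 1 and 7 of these calls, in the same order. Positions are those of GRCm38.p6, the assembly named mm10 by the submitters.

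Panel genes lie at chromosome 11 98412484 to 98437716 (Erbb2), chromosome 10 24595442 to 24598683 (Ctgf), chromosome 3 145646971 to 145649985 (Cyr61), chromosome 19 36111965 to 36119844 (Ankrd1), chromosome 2 13574311 to 13582826 (Vim), chromosome 4 148000722 to 148002074 (Nppa), chromosome 4 147985786 to 147987205 (Nppb), chromosome 14 54941921 to 54968017 (Myh6), chromosome 14 54970684 to 54994626 (Myh7), chromosome 8 123891758 to 123894775 (Acta1), chromosome 11 94936224 to 94953042 (Col1a1) and chromosome 3 54359267 to 54391041 (Postn), all in GRCm38.p6.

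No library was left out. Between libraries of the same group, chi-square per degree of freedom of the recovered reads was 9.30 to 36.9, so that no 2 libraries were copies of 1 library, and the lowest correlation of log2 values was 0.957 in the same group and 0.906 between groups. Sex was read from Xist and Ddx3y transcripts: females numbered 1 of 4 WT sham, 2 of 4 OE sham, 2 of 4 WT infarcted and 3 of 4 OE infarcted hearts. RA numbers of 14 and above fell to WT sham replicates 3 and 4, OE sham replicate 4 and WT infarcted replicate 4. Sex and RA number were added to the model as alternatives. Alternatives added after the data were seen were terms for lung and thymus transcripts and a fit of RA 1 to 12 alone.

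In simulated data of the same size with 50 genes changed per fold, limma recovered 42% of 1.5-fold, 80% of 2-fold and 86% of 4-fold changes for OE in sham hearts, with 5.41% false calls. OE in infarcted hearts gave 48%, 80% and 94%, with 3.95% false calls. MI gave 44%, 68% and 96% (4.96%) in WT and 50%, 84% and 92% (4.38%) in OE hearts. The interaction gave 16%, 70% and 84% (3.48%). Among 33 simulated lists, 1 was called falsely. Genes were drawn independently there, so the preset correlation was not tested. A test over 4 against 4 libraries has 70 splits and a smallest exact two-sided p of 0.0286.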

Results

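Transcripts of 16 hearts were compared to ask what ERBB2 overexpression does to the adult mouse heart with and without an infarct, and whether YAP target, EMT, cell-cycle and metabolic genes move with it. Recovered reads were 11939093, 12754880, 13764534 and 14886191 in the 4 WT sham libraries and 15907991, 15669405, 15382099 and 17095751 in the 4 OE sham libraries. WT infarcted libraries held 12747697, 13900173, 14297128 and 13693395 reads and OE infarcted libraries 17468914, 17401717, 14998464 and 16360283. The 100 most abundant genes took 30.1 ± 0.69% of reads in WT sham, 26.2 ± 0.71% in OE sham, 28.4 ± 0.45% in WT infarcted and 25.8 ± 0.54% in OE infarcted hearts (mean ± SD, n = 4 each). Deposited size factors ran from 0.774 to 0.935 in WT sham, 1.05 to 1.25 in OE sham, 0.830 to 0.949 in WT infarcted and 1.08 to 1.30 in OE infarcted hearts. The 1st principal component held 44.2% of the variance and had OE and WT hearts on opposite sides of 0, and the 2nd held 16.9%. Infarcted hearts lay below 0 on the 2nd but for WT infarcted replicate 1 and OE infarcted replicate 4. These held at most 3 reads of the lung surfactant gene Sftpc, but OE infarcted replicate 1 held 6 and lay at -20.0.

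**Figure D1:**
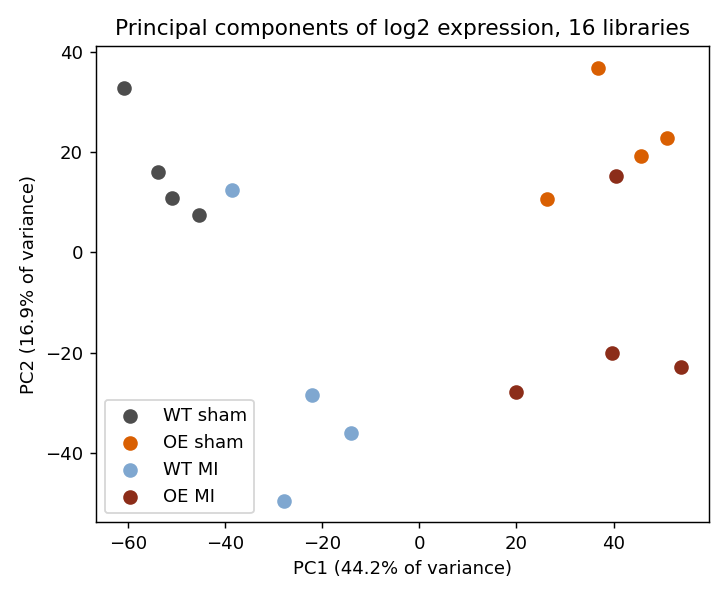
Principal components of log2(value + 1) of the 14298 tested genes, with 1 point per library (n = 4 per group). The horizontal axis is component 1 (44.2% of variance) and the vertical axis component 2 (16.9%), both in arbitrary score units.

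Erbb2 transcripts marked the genotype in each library. Erbb2 stood at 259.6, 248, 245 and 259 normalized reads in the WT sham hearts and 222, 276, 204 and 307 in the WT infarcted hearts, in the order of replicates 1 to 4. In OE hearts Erbb2 reached 1946, 792, 2529.9 and 1783 after sham surgery and 793, 1105, 1808 and 2504 after infarction. The mean was 124 ± 49.6 CPM in OE sham against 15.9 ± 0.74 CPM in WT sham hearts (7.77-fold, n = 4 each, exact p = 0.0286). In infarcted hearts Erbb2 was 111 ± 51.3 against 16.7 ± 3.67 CPM (6.63-fold, n = 4 each, exact p = 0.0286). MI against sham gave an exact p of 0.714 for Erbb2 in WT and 0.771 in OE hearts. In limma the Erbb2 log2 fold change was 2.68 in sham hearts (SE 0.33, adjusted p = 9.99e-06) and 2.50 in infarcted hearts (SE 0.33, adjusted p = 5.53e-05).

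ERBB2 overexpression in uninjured hearts went with more matrix transcripts and fewer mitochondrial ones. Postn, which encodes the matrix protein periostin, rose from 1331 ± 165 to 16699.6 ± 3336 (log2 fold change 3.63, SE 0.19, adjusted p = 1.37e-08), in normalized reads, mean ± SD, n = 4 each. Col1a1, a chain of fibrillar collagen, rose from 2549 ± 537 to 19384 ± 2886 (log2 fold change 2.94, SE 0.27, adjusted p = 5.90e-07). Uqcrc1, a core subunit of respiratory complex III, fell from 21663 ± 1058 to 10563 ± 724 (log2 fold change -1.04, SE 0.07, adjusted p = 7.65e-08). Eci1, an enzyme of fatty acid oxidation, fell from 4519 ± 433 to 1429 ± 237 (log2 fold change -1.67, SE 0.13, adjusted p = 1.77e-07). Of 14298 tested genes, 7051 passed in OE against WT sham hearts, 3554 up and 3497 down, of which 1059 up and 836 down changed at least 2-fold. Library totals in place of the deposited factors moved the median of all genes by 0.16 log2 and gave 5171 up and 2374 down. The count was 7035 with lung and thymus terms and 5728 for RA 1 to 12 alone, both added after the data were seen. The authors' deposited table calls 6970 genes here, 3447 up and 3523 down, 6727 of them passing in both.

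Fibrillar matrix genes moved together, with 27 up, 0 down and 1 not passing (the same adjusted over the list alone), median 2.78, adjusted p = 7.37e-17, and adjusted p = 0.136 with an estimated correlation. Basement membrane genes counted 12 up, 0 down and 2 not passing (the same adjusted over the list alone), median 0.75, adjusted p = 8.14e-07, and adjusted p = 0.130 with an estimated correlation. Lamb1 (0.73, adjusted p = 3.35e-07) rose. EMT genes counted 24 up, 0 down and 4 not passing (26 up and 0 down adjusted over the list alone), median 1.25, adjusted p = 2.34e-12, and adjusted p = 0.130 with an estimated correlation. Mmp2, a gelatinase that cleaves matrix, rose from 1786 ± 182 to 9356 ± 1322 (log2 fold change 2.38, SE 0.13, adjusted p = 1.99e-08), and Mmp14, its membrane-bound activator, rose by 2.88 (adjusted p = 1.68e-07). Vim, an intermediate filament of mesenchymal cells, rose from 6361 ± 414 to 11093 ± 592 (log2 fold change 0.80, SE 0.10, adjusted p = 1.29e-05). Actin and adhesion genes counted 23 up, 1 down and 2 not passing (the same adjusted over the list alone), median 0.79, adjusted p = 1.03e-08, and adjusted p = 0.195 with an estimated correlation. Anxa2 (1.83, adjusted p = 1.48e-06) rose and Rdx (-0.35, adjusted p = 7.33e-05), a membrane-to-actin linker, fell. Fibroblast markers counted 8 up, 1 down and 3 not passing (the same adjusted over the list alone), median 0.93, adjusted p = 6.56e-05, and adjusted p = 0.184 with an estimated correlation. Col6a1 (2.30, adjusted p = 4.14e-08) rose and Gsn (-0.80, adjusted p = 0.00433), an actin-severing protein, fell. Lung Sftpc was at or under 3 reads in each sham library.

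YAP target genes counted 11 up, 3 down and 8 not passing (the same adjusted over the list alone), median 0.48, adjusted p = 0.0120, and adjusted p = 0.148 with an estimated correlation. Ctgf, a secreted matricellular protein and YAP target, rose from 1816 ± 264 to 13656 ± 4497 (log2 fold change 2.85, SE 0.41, adjusted p = 3.68e-05). Ankrd1, a stress-responsive nuclear and sarcomeric protein, rose from 21926 ± 7282 to 85175 ± 4832 (log2 fold change 2.01, SE 0.34, adjusted p = 0.000156). Tgfb2 rose as well (1.91, adjusted p = 9.49e-07), whereas F3, the initiator of coagulation, fell (-0.71, adjusted p = 0.00895). Cyr61 stood at 936 ± 216 and 1941 ± 737 (log2 fold change 0.98, SE 0.38, adjusted p = 0.0433), a call lost without each of WT sham replicates 1 (adjusted p = 0.0610), 3 (0.0658) and 4 (0.124), OE sham replicates 1 (0.108), 2 (0.128) and 3 (0.0795), and WT infarcted replicate 2 (0.0504). ERK feedback and ETS target genes, which respond to signalling below receptor tyrosine kinases, counted 18 up, 0 down and 3 not passing (19 up and 0 down adjusted over the list alone), median 1.04, adjusted p = 8.08e-08, and adjusted p = 0.130 with an estimated correlation. Phlda1 rose from 348 ± 57.7 to 3006 ± 714 (log2 fold change 3.09, SE 0.21, adjusted p = 6.06e-08). Immediate-early and heat shock genes counted 11 up, 0 down and 7 not passing (the same adjusted over the list alone), median 1.13, adjusted p = 0.00112, and adjusted p = 0.5003 with an estimated correlation. Egr1 (3.45, adjusted p = 3.34e-05) and Egr2 (4.21, adjusted p = 1.18e-05) rose.

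Mitotic genes were higher in OE sham hearts, and G2/M and cytokinesis genes counted 24 up, 1 down and 0 not passing (the same adjusted over the list alone), median 1.84, adjusted p = 1.03e-08, and adjusted p = 0.291 with an estimated correlation. Ccna2, the cyclin of S phase and early mitosis, rose from 28.9 ± 8.14 to 137 ± 39.2 (log2 fold change 2.21, SE 0.28, adjusted p = 1.30e-05). Cenpf, a kinetochore protein, was the member that fell, from 441 ± 124 to 104 ± 10.3 (log2 fold change -2.03, SE 0.29, adjusted p = 3.58e-05). S-phase genes counted 15 up, 0 down and 9 not passing (the same adjusted over the list alone), median 0.65, adjusted p = 0.000694, and adjusted p = 0.452 with an estimated correlation. Tyms (1.23, adjusted p = 4.06e-05) rose.

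Cardiomyocyte transcripts split in direction. Nppa, the atrial natriuretic peptide that ventricles express in fetal life and under stress, rose from 28178 ± 12821 to 200045 ± 31391 (log2 fold change 2.93, SE 0.33, adjusted p = 4.15e-06), and Nppb rose from 2529 ± 1684 to 19153 ± 3680.3 (log2 fold change 3.19, SE 0.40, adjusted p = 1.01e-05). Myh6, the adult myosin heavy chain of the mouse ventricle, fell from 397551 ± 50430.0 to 192669 ± 18412 (log2 fold change -1.04, SE 0.16, adjusted p = 6.58e-05), while fetal Myh7 rose from 11474 ± 4898 to 21257 ± 3680.4 (log2 fold change 1.03, SE 0.33, adjusted p = 0.0163). WT sham replicate 4 was low in Myh7, at 4259 normalized reads, and without it the log2 fold change was 0.60 and still passed. Skeletal actin Acta1 had log2 fold change 0.48, SE 0.55, adjusted p = 0.488. Fetal and dedifferentiation genes counted 9 up, 2 down and 4 not passing (the same adjusted over the list alone), median 1.03, adjusted p = 0.00544, and adjusted p = 0.148 with an estimated correlation. Actn1 (1.46, adjusted p = 7.93e-06) rose and Acta2 (-1.03, adjusted p = 0.00579), smooth muscle actin, fell. Sarcomere genes counted 3 up, 15 down and 5 not passing (the same adjusted over the list alone), median -0.43, adjusted p = 0.000694, and adjusted p = 0.344 with an estimated correlation. Tnni3 (-1.25, adjusted p = 2.21e-07) fell and Des (1.05, adjusted p = 1.37e-05), an intermediate filament of muscle, rose. Calcium handling and ion channel genes counted 0 up, 18 down and 6 not passing (the same adjusted over the list alone), median -0.96, adjusted p = 2.05e-07, and adjusted p = 0.136 with an estimated correlation. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 295168 ± 19563 to 86990.0 ± 13917 (log2 fold change -1.77, SE 0.16, adjusted p = 6.46e-07).

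Each tested gene of oxidative phosphorylation was lower in OE sham hearts: 0 up, 29 down and 0 not passing (the same adjusted over the list alone), median -0.86, adjusted p = 9.11e-19, and adjusted p = 0.148 with an estimated correlation. TCA cycle genes counted 0 up, 22 down and 0 not passing (the same adjusted over the list alone), median -0.87, adjusted p = 2.81e-16, and adjusted p = 0.148 with an estimated correlation. Fh1 (-1.03, adjusted p = 1.07e-07) fell. Fatty acid oxidation genes counted 0 up, 24 down and 1 not passing (the same adjusted over the list alone), median -1.32, adjusted p = 3.75e-15, and adjusted p = 0.148 with an estimated correlation. Macrophage markers counted 9 up, 0 down and 7 not passing (12 up and 0 down adjusted over the list alone), median 0.65, adjusted p = 0.00544, and adjusted p = 0.5003 with an estimated correlation. Lgals3 (2.12, adjusted p = 0.000626) rose. Inflammatory cytokine and chemokine genes counted 8 up, 0 down and 8 not passing (the same adjusted over the list alone), median 1.096, adjusted p = 0.0407, and adjusted p = 0.398 with an estimated correlation. Cxcl10 (2.33, adjusted p = 0.000103) rose. The cytokine list was not called without WT sham replicate 3 (adjusted p = 0.0564), WT sham replicate 4 (0.0592), OE sham replicate 3 (0.0623) or WT infarcted replicate 1 (0.0520), nor on library totals (0.203) or for RA 1 to 12 alone (0.147).

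Among the largest rises without overlap of libraries were F2rl2, a protease-activated receptor, from 1.61 ± 3.23 to 697 ± 264 (log2 fold change 8.63, SE 0.70, adjusted p = 2.21e-07) and Frem1 (5.85, adjusted p = 8.79e-09). Among the largest falls were Efnb3, an ephrin ligand, from 2404 ± 1371 to 78.5 ± 28.8 (log2 fold change -4.81, SE 0.50, adjusted p = 1.82e-06) and Acsm5 (-4.57, adjusted p = 1.34e-05). Skeletal muscle Myh1 was at 1032 normalized reads in WT sham replicate 1 and at or under 7.61 in the other sham hearts, and Ckm (-1.84, adjusted p = 3.07e-08), a creatine kinase of heart and skeletal muscle, fell.

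**Figure D2:**
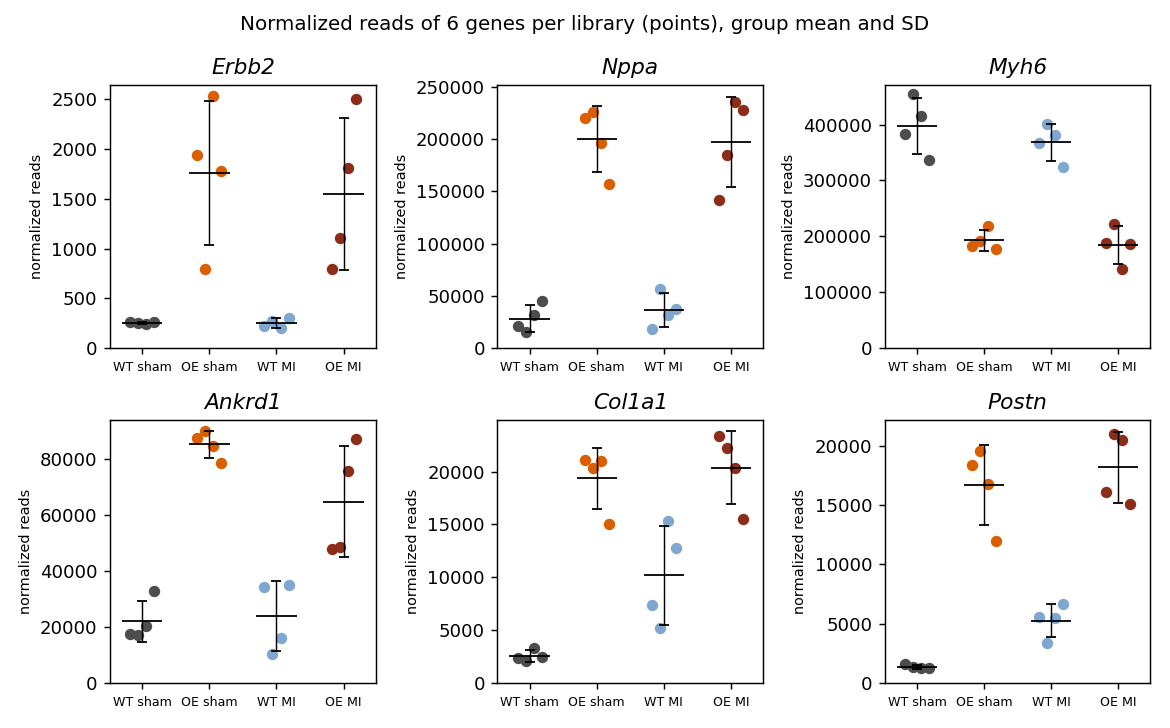
Normalized reads (vertical axes, linear) of Erbb2, Nppa, Myh6, Ankrd1, Col1a1 and Postn, with 1 point per library, lines at group means and error bars of 1 SD (n = 4 per group). Postn averaged 1331 in WT sham and 5253 in WT infarcted hearts.

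After infarction, OE hearts again held more matrix and mitotic transcripts and fewer mitochondrial ones than WT hearts. Postn rose from 5253 ± 1371 to 18184 ± 3025 (log2 fold change 1.82, SE 0.19, adjusted p = 7.95e-06), in normalized reads, mean ± SD, n = 4 each. Nppa rose from 36125 ± 16133 to 197184 ± 43316 (log2 fold change 2.54, SE 0.33, adjusted p = 4.72e-05), and Myh6 fell from 368084 ± 32539 to 184590.1 ± 33218 (log2 fold change -1.01, SE 0.16, adjusted p = 0.000226). Cox7a1, the muscle form of a cytochrome c oxidase subunit, fell from 8237 ± 819 to 2842 ± 333 (log2 fold change -1.54, SE 0.10, adjusted p = 6.41e-07). Mki67, a marker of cycling cells, rose from 159.7 ± 20.4 to 564 ± 211 (log2 fold change 1.76, SE 0.28, adjusted p = 0.000214). In total 4554 genes passed, 2218 up and 2336 down, with 495 up and 461 down at least 2-fold. Library totals moved the median of all genes by 0.13 log2 and gave 3851 up and 1556 down. The count was 1320 with lung and thymus terms and 4340 for RA 1 to 12 alone, both added after the data were seen. The authors' deposited table calls 4541 genes, 2215 up and 2326 down, of which 4369 pass in both.

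Among panel genes, Ctgf (1.502, adjusted p = 0.0106), Ankrd1 (1.57, adjusted p = 0.00230), Vim (0.36, adjusted p = 0.0132), Nppb (1.71, adjusted p = 0.00392) and Col1a1 (1.11, adjusted p = 0.00495) passed in infarcted OE against WT hearts. Values for Cyr61 (0.22, adjusted p = 0.712), Myh7 (0.41, adjusted p = 0.366) and Acta1 (-0.22, adjusted p = 0.798) did not pass. Lung and thymus terms ended 54 of the 112 calls of eligible genes, among them Ctgf (0.84 with the terms, adjusted p = 0.405), Ankrd1 (1.25, 0.109), Vim (0.42, 0.103), Nppb (1.29, 0.186) and Col1a1 (1.08, 0.107). Fibrillar matrix genes counted 23 up, 0 down and 5 not passing (the same adjusted over the list alone), median 1.05, adjusted p = 6.59e-11, and adjusted p = 0.217 with an estimated correlation. EMT genes counted 19 up, 0 down and 9 not passing (the same adjusted over the list alone), median 0.72, adjusted p = 2.12e-09, and adjusted p = 0.120 with an estimated correlation. Ncam1 (2.12, adjusted p = 6.74e-06) and Mmp2 (1.12, adjusted p = 1.78e-05) rose. Basement membrane genes counted 11 up, 0 down and 3 not passing (the same adjusted over the list alone), median 0.51, adjusted p = 4.96e-07, and adjusted p = 0.120 with an estimated correlation. Actin and adhesion genes counted 13 up, 1 down and 12 not passing (14 up and 1 down adjusted over the list alone), median 0.41, adjusted p = 1.01e-05, and adjusted p = 0.331 with an estimated correlation. Fibroblast markers counted 6 up, 1 down and 5 not passing (the same adjusted over the list alone), median 0.38, adjusted p = 0.00899, and adjusted p = 0.368 with an estimated correlation. YAP target genes counted 6 up, 2 down and 14 not passing, 7 up and 2 down adjusted over the list alone, median 0.20, adjusted p = 0.106. Fetal and dedifferentiation genes counted 5 up, 1 down and 9 not passing, median 0.41, adjusted p = 0.0522.

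G2/M and cytokinesis genes counted 24 up, 1 down and 0 not passing (the same adjusted over the list alone), median 1.60, adjusted p = 6.26e-12, and adjusted p = 0.237 with an estimated correlation. Ect2 (1.72, adjusted p = 9.88e-05) rose and Cenpf (-1.27, adjusted p = 0.00354) fell. S-phase genes counted 12 up, 0 down and 12 not passing (13 up and 0 down adjusted over the list alone), median 0.62, adjusted p = 8.18e-06, and adjusted p = 0.331 with an estimated correlation. With lung and thymus terms medians were 1.17 for the G2/M (adjusted p = 6.95e-10) and 0.38 for the S-phase list (0.00688). OE infarcted replicate 3 was highest both in Rag1, a recombinase of thymocytes (422 normalized reads), and in the mean log2 value of G2/M genes (7.47, against 6.51 to 6.87 in the other OE infarcted libraries). ERK feedback and ETS target genes counted 14 up, 0 down and 7 not passing (17 up and 0 down adjusted over the list alone), median 0.81, adjusted p = 2.00e-07, and adjusted p = 0.120 with an estimated correlation. Oxidative phosphorylation genes counted 0 up, 29 down and 0 not passing (the same adjusted over the list alone), median -0.79, adjusted p = 2.13e-26, and adjusted p = 0.120 with an estimated correlation. TCA cycle genes counted 0 up, 22 down and 0 not passing (the same adjusted over the list alone), median -0.77, adjusted p = 2.45e-21, and adjusted p = 0.120 with an estimated correlation. Fatty acid oxidation genes counted 0 up, 24 down and 1 not passing (the same adjusted over the list alone), median -1.12, adjusted p = 2.85e-19, and adjusted p = 0.120 with an estimated correlation. Calcium handling and ion channel genes counted 1 up, 17 down and 6 not passing (2 up and 18 down adjusted over the list alone), median -0.63, adjusted p = 4.91e-07, and adjusted p = 0.120 with an estimated correlation. Sarcomere genes counted 2 up, 13 down and 8 not passing (2 up and 15 down adjusted over the list alone), median -0.43, adjusted p = 0.000142, and adjusted p = 0.317 with an estimated correlation. Among the largest effects were those of F2rl2 (5.99, adjusted p = 1.66e-05) and Acsm5 (-3.98, adjusted p = 0.000130).

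In infarcted OE against WT hearts, T and NK cell markers counted 4 up, 0 down and 4 not passing (5 up and 0 down adjusted over the list alone), median 1.73, adjusted p = 0.0126, and adjusted p = 0.393 with an estimated correlation. Lck, a kinase of T cells and thymocytes, stood at 11.3 ± 4.61 and 120.5 ± 82.3 (log2 fold change 2.93, SE 0.58, adjusted p = 0.00133). The thymocyte recombinase Rag1 was at 256, 0, 422 and 162 normalized reads in OE infarcted replicates 1 to 4 and at or under 4 reads in each sham library. The T and NK list was not called without OE infarcted replicate 1 (adjusted p = 0.0512) or 3 (0.0578), on library totals (0.0559) or with lung and thymus terms (median -0.01, 0.667). Immediate-early and heat shock genes counted 5 up, 0 down and 13 not passing (the same adjusted over the list alone), median 0.46, adjusted p = 0.0126, and adjusted p = 0.695 with an estimated correlation. Egr2 (3.20, adjusted p = 0.000363) rose, and the list was not called without WT infarcted replicate 1 (0.0862) or 4 (0.0718), with lung and thymus terms (median 0.19, 0.157), on library totals (0.0773) or for RA 1 to 12 alone (0.0934). Glycolysis genes counted 8 up, 3 down and 6 not passing (the same adjusted over the list alone), median 0.22, adjusted p = 0.0126, and adjusted p = 0.368 with an estimated correlation. With lung and thymus terms the glycolysis list had a median of 0.17 and an adjusted p of 0.136.

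In WT hearts matrix genes were higher 2 weeks after infarction than after sham surgery. Postn rose from 1331 ± 165 to 5253 ± 1371 (log2 fold change 1.95, SE 0.19, adjusted p = 0.000196), in normalized reads, mean ± SD, n = 4 each. Col1a1 rose from 2549 ± 537 to 10178 ± 4696 (log2 fold change 1.89, SE 0.27, adjusted p = 0.00115), and Col3a1, the collagen that partners type I fibrils, rose from 5354 ± 962 to 25532 ± 8439.5 (log2 fold change 2.21, SE 0.23, adjusted p = 0.000196). Cthrc1, a secreted product of activated fibroblasts, rose from 4.89 ± 2.03 to 137 ± 79.99 (log2 fold change 4.44, SE 0.54, adjusted p = 0.000482). Spp1, which encodes osteopontin, rose from 20.6 ± 8.19 to 236 ± 125 (log2 fold change 3.38, SE 0.47, adjusted p = 0.00111). In the same libraries lung surfactant Sftpc was at 3.62, 5038, 1187 and 4018 normalized reads in WT infarcted replicates 1 to 4.

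In WT hearts 1008 genes passed for MI against sham, 709 up and 299 down, with 263 up and 5 down at least 2-fold. Library totals gave 977 up and 70 down, and factors from trimmed means, outside the plan, 804 up and 182 down. The count fell to 95 with lung and thymus terms and to 112 for RA 1 to 12 alone, both added after the data were seen. With the terms all 709 genes up stayed positive, their median log2 fold change going from 0.81 to 0.76 and their median SE from 0.1796 to 0.227. The count for WT hearts ran from 276 without WT sham replicate 2 to 1874 without WT infarcted replicate 1. DESeq2 on the recovered reads called 1693, edgeR 995 and voom 453. The authors' deposited table calls 1445, 943 up and 502 down, 987 of them passing in both.

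Fibrillar matrix genes in WT infarcts counted 25 up, 0 down and 3 not passing (28 up and 0 down adjusted over the list alone), median 1.65, adjusted p = 2.81e-30, and adjusted p = 0.0743 with an estimated correlation. Fibroblast markers counted 10 up, 0 down and 2 not passing (the same adjusted over the list alone), median 0.78, adjusted p = 1.00e-10, and adjusted p = 0.0743 with an estimated correlation. EMT genes counted 12 up, 0 down and 16 not passing (15 up and 1 down adjusted over the list alone), median 0.65, adjusted p = 2.13e-11, and adjusted p = 0.112 with an estimated correlation. Mmp2 (1.24, adjusted p = 0.000196) and Tnc (2.88, adjusted p = 0.00105) rose. YAP target genes counted 4 up, 0 down and 18 not passing (7 up and 0 down adjusted over the list alone), median 0.30, adjusted p = 0.000691, and adjusted p = 0.0743 with an estimated correlation. Among panel genes Vim rose (0.64, adjusted p = 0.00284). Values for Ctgf (1.31, adjusted p = 0.0624), Cyr61 (0.74, adjusted p = 0.232), Ankrd1 (-0.01, adjusted p = 0.989), Nppa (0.35, adjusted p = 0.527), Nppb (0.99, adjusted p = 0.131), Myh6 (-0.11, adjusted p = 0.707), Myh7 (0.63, adjusted p = 0.234), Acta1 (-0.05, adjusted p = 0.969) and Erbb2 (-0.02, adjusted p = 0.977) did not pass. Actin and adhesion genes counted 6 up, 0 down and 20 not passing (13 up and 0 down adjusted over the list alone), median 0.34, adjusted p = 3.47e-08, and adjusted p = 0.230 with an estimated correlation. Basement membrane genes counted 4 up, 0 down and 10 not passing (8 up and 0 down adjusted over the list alone), median 0.24, adjusted p = 0.000970, and adjusted p = 0.205 with an estimated correlation. Lung and thymus terms ended 48 of the 63 calls of eligible genes, among them Vim (0.58 with the terms, adjusted p = 0.0714), Runx1 (1.68, 0.0765), Nupr1 (1.37, 0.0672) and Ndufs8 (-0.17, 0.274). Calls that stayed included Postn (2.02, 0.00863), Col3a1 (2.27, 0.00863) and Col1a1 (2.04, 0.0267).

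Macrophage markers in WT infarcts counted 9 up, 0 down and 7 not passing (12 up and 0 down adjusted over the list alone), median 0.65, adjusted p = 4.68e-09, and adjusted p = 0.205 with an estimated correlation. Inflammatory cytokine and chemokine genes counted 3 up, 0 down and 13 not passing (7 up and 0 down adjusted over the list alone), median 0.82, adjusted p = 0.000643, and adjusted p = 0.205 with an estimated correlation. Interferon-stimulated genes counted 2 up, 0 down and 18 not passing (the same adjusted over the list alone), median 0.37, adjusted p = 0.000189, and adjusted p = 0.311 with an estimated correlation. Epicardial and mesothelial markers counted 3 up, 0 down and 8 not passing (10 up and 0 down adjusted over the list alone). Their median was 1.16 (0.73 with lung and thymus terms), adjusted p = 2.41e-06, and adjusted p = 0.211 with an estimated correlation. Neutrophil markers counted 0 of 9 passing (1 up and 0 down adjusted over the list alone), median 1.57, adjusted p = 0.00816, and adjusted p = 0.322 with an estimated correlation. Its call was lost without WT infarcted replicate 3 (adjusted p = 0.0537) or 4 (0.0653). Immediate-early and heat shock genes counted 0 of 18 passing (0 adjusted over the list alone), median 0.46, adjusted p = 0.000674, and adjusted p = 0.426 with an estimated correlation. That call ended without WT infarcted replicate 3 (0.0537). Fetal and dedifferentiation genes counted 1 up, 0 down and 14 not passing (2 up and 0 down adjusted over the list alone), median 0.35, adjusted p = 0.0214, and adjusted p = 0.230 with an estimated correlation. Runx1 (1.57, adjusted p = 0.00840) rose, and the list was not called without WT sham replicate 2 (0.0670) or WT infarcted replicate 4 (0.0659), with lung and thymus terms (median 0.27, 0.116) or on library totals (0.0670). ERK feedback and ETS target genes counted 1 up, 1 down and 19 not passing (2 up and 1 down adjusted over the list alone), median 0.31, adjusted p = 0.0108, and adjusted p = 0.313 with an estimated correlation. Serine synthesis and ATF4 target genes counted 3 up, 1 down and 19 not passing (4 up and 1 down adjusted over the list alone), median 0.22, adjusted p = 0.0107, and adjusted p = 0.230 with an estimated correlation. Nupr1 (1.49, adjusted p = 0.00336) rose.

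Cardiomyocyte and mitochondrial lists had negative medians in WT infarcts. Oxidative phosphorylation genes counted 0 up, 4 down and 25 not passing (0 up and 20 down adjusted over the list alone), median -0.23, adjusted p = 1.00e-10, and adjusted p = 0.298 with an estimated correlation. TCA cycle genes counted 0 up, 4 down and 18 not passing (0 up and 19 down adjusted over the list alone), median -0.23, adjusted p = 1.58e-09, and adjusted p = 0.252 with an estimated correlation. Fatty acid oxidation genes counted 0 of 25 passing (0 adjusted over the list alone), median -0.28, adjusted p = 5.92e-06, and adjusted p = 0.350 with an estimated correlation. Calcium handling and ion channel genes counted 0 up, 2 down and 22 not passing (0 up and 8 down adjusted over the list alone), median -0.30, adjusted p = 9.94e-07, and adjusted p = 0.176 with an estimated correlation. Sarcomere genes counted 0 up, 1 down and 22 not passing (0 adjusted over the list alone), median -0.15, adjusted p = 0.00214, and adjusted p = 0.328 with an estimated correlation. For RA 1 to 12 alone the sarcomere list had an adjusted p of 0.0908. Ndufs8 fell from 4403 ± 117 to 3717 ± 209.8 (log2 fold change -0.25, SE 0.06, adjusted p = 0.0222), a call lost without WT sham replicate 2 (adjusted p = 0.0611), WT sham replicate 4 (0.0629), WT infarcted replicate 2 (0.0571) or WT infarcted replicate 4 (0.0576). G2/M and cytokinesis genes counted 1 up, 0 down and 24 not passing (10 up and 0 down adjusted over the list alone), median 0.68, adjusted p = 3.29e-07, and adjusted p = 0.313 with an estimated correlation. S-phase genes counted 1 up, 0 down and 23 not passing, median 0.00, adjusted p = 0.494.

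**Figure D3:**
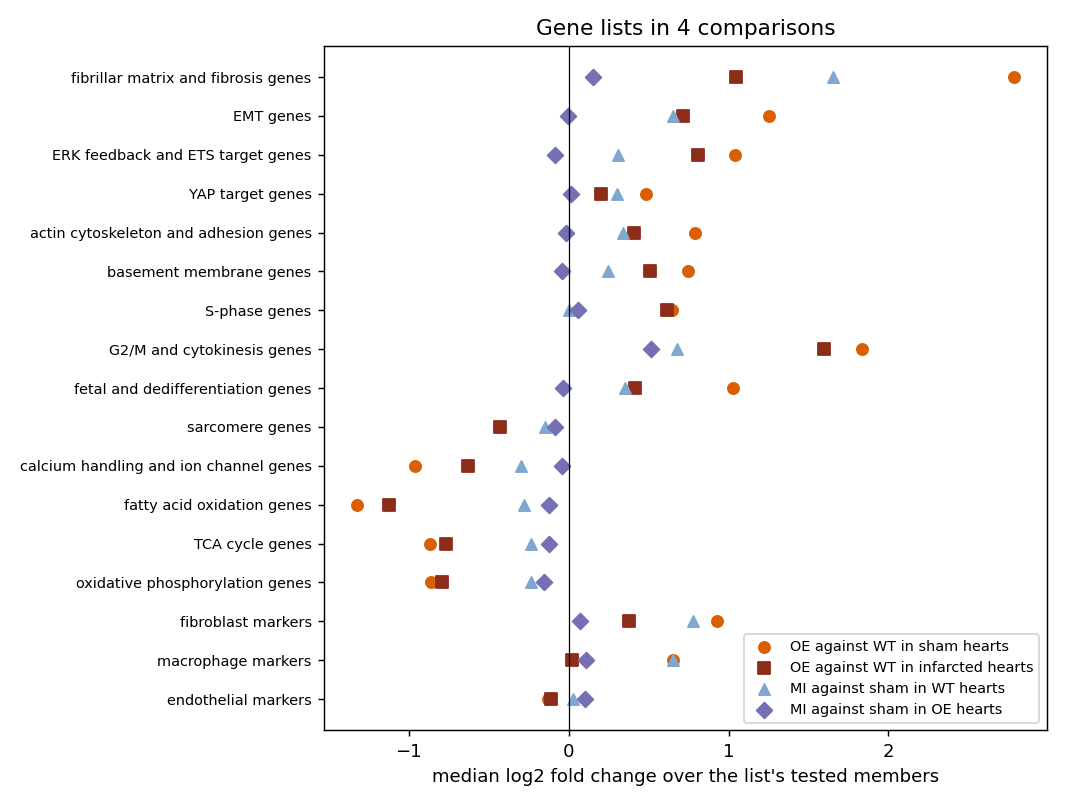
Median log2 fold change of the members of 17 gene lists (horizontal axis) in the 4 comparisons of groups, with 1 point per list and comparison, marker shape and color for the comparison, and no error bars. Fibrillar matrix genes had medians of 2.78 for OE in sham hearts and 1.65 for MI in WT hearts.

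In OE hearts no fibrillar matrix gene passed for MI. Postn stood at 16699.6 ± 3336 in OE sham and 18184 ± 3025 in OE infarcted hearts (log2 fold change 0.13, SE 0.19, adjusted p = 0.846), in normalized reads, mean ± SD, n = 4 each. Col1a1 stood at 19384 ± 2886 and 20365 ± 3469.7 (log2 fold change 0.07, SE 0.27, adjusted p = 0.949), and Eln, which encodes elastin, at 3527 ± 1419 and 6777 ± 2840.0 (log2 fold change 0.95, SE 0.34, adjusted p = 0.422). Ctgf (-0.04, adjusted p = 0.983), Cyr61 (-0.03, adjusted p = 0.986), Ankrd1 (-0.44, adjusted p = 0.663), Vim (0.20, adjusted p = 0.513), Nppa (-0.03, adjusted p = 0.981), Nppb (-0.49, adjusted p = 0.694), Myh6 (-0.08, adjusted p = 0.901), Myh7 (0.02, adjusted p = 0.989), Acta1 (-0.75, adjusted p = 0.646) and Erbb2 (-0.20, adjusted p = 0.869) did not pass either. The only call by limma was Ret, a receptor tyrosine kinase of neural crest lineages, which fell from 141 ± 15.9 to 74.1 ± 7.89 (log2 fold change -0.92, SE 0.12, adjusted p = 0.0259). The Ret call was lost without each of WT sham replicates 1 to 4 (adjusted p = 0.0532, 0.0595, 0.0599 and 0.0561), OE sham replicates 1, 2 and 3 (0.162, 0.0740 and 0.170), WT infarcted replicate 1 (0.0504) and OE infarcted replicates 1 and 3 (0.0786 and 0.160). At an unadjusted p below 0.05, 1448 genes stood beside that 1 call. DESeq2 on the recovered reads called 90 genes, voom 2 and edgeR 1, and 85 genes, 63 up and 22 down, pass in the authors' deposited table, 1 of them here. No gene passed with lung and thymus terms or for RA 1 to 12 alone, both added after the data were seen. The count was 10 without OE infarcted replicate 2, 3 without OE sham replicate 4, 2 without WT infarcted replicate 2 or OE infarcted replicate 4, and 0 without each of WT sham replicates 1 to 4, OE sham replicates 1 to 3, WT infarcted replicate 1 and OE infarcted replicate 3.

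Neutrophil and T and NK cell markers had the largest medians of the tested lists for MI in OE hearts. T and NK cell markers counted 0 of 8 passing (8 up and 0 down adjusted over the list alone), median 2.001, adjusted p = 8.12e-11, and adjusted p = 0.207 with an estimated correlation. Lck stood at 11.4 ± 5.30 and 120.5 ± 82.3 (log2 fold change 2.93, SE 0.58, adjusted p = 0.257), beside the Rag1 reads given above. Lung Sftpc in these hearts was at 4.63, 2744, 1097 and 0. Neutrophil markers counted 0 of 9 passing (0 adjusted over the list alone), median 2.05, adjusted p = 6.16e-06, and adjusted p = 0.475 with an estimated correlation. Epicardial and mesothelial markers counted 0 of 11 passing (7 up and 0 down adjusted over the list alone), median 1.13, adjusted p = 3.80e-06, and adjusted p = 0.591 with an estimated correlation. With lung and thymus terms the median was 0.32 (adjusted p = 0.0956) for T and NK, 1.28 (0.0565) for neutrophil and 0.70 (0.0956) for epicardial and mesothelial markers. Skeletal muscle markers counted 0 of 10 passing (0 adjusted over the list alone), median 1.28, adjusted p = 0.00776, and adjusted p = 0.676 with an estimated correlation. It did not pass without OE infarcted replicate 1 (adjusted p = 0.155), the OE infarcted library with Myh1 at 468 normalized reads. Adipocyte markers counted 0 of 10 passing (0 adjusted over the list alone), median 1.60, adjusted p = 0.0496, and adjusted p = 0.750 with an estimated correlation. This list was not called without OE sham replicates 2 or 3, WT infarcted replicates 3 or 4, or OE infarcted replicates 2 or 3 (0.0507 to 0.309), with lung and thymus terms (median 0.12, 0.952) or on library totals (0.127).

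For MI in OE hearts, G2/M and cytokinesis genes counted 0 of 25 passing (0 adjusted over the list alone), median 0.51, adjusted p = 2.06e-09, and adjusted p = 0.676 with an estimated correlation. Its median was -0.03 with lung and thymus terms (adjusted p = 0.968). Oxidative phosphorylation genes counted 0 of 29 passing (0 adjusted over the list alone), median -0.16, adjusted p = 8.15e-10, and adjusted p = 0.676 with an estimated correlation. TCA cycle genes counted 0 of 22 passing (0 adjusted over the list alone), median -0.12, adjusted p = 5.21e-05, and adjusted p = 0.676 with an estimated correlation. With those terms their medians were -0.06 (adjusted p = 0.137) and 0.02 (0.808). Interferon-stimulated genes counted 0 of 20 passing (0 adjusted over the list alone), median 0.20, adjusted p = 0.00155, and adjusted p = 0.676 with an estimated correlation. Its call was lost without OE sham replicate 2 (adjusted p = 0.0538) or OE infarcted replicate 2 (0.0746). Fibrillar matrix genes counted 0 of 28 passing (0 adjusted over the list alone), median 0.15, adjusted p = 0.0223, and adjusted p = 0.750 with an estimated correlation. That call ended without OE sham replicate 4 (0.354), OE infarcted replicate 1 (0.190) or 3 (0.0926), with lung and thymus terms (median 0.13, 0.571), on library totals (0.0711) or for RA 1 to 12 alone (0.379). Sarcomere genes counted 0 of 23 passing (0 up and 1 down adjusted over the list alone), median -0.09, adjusted p = 0.0496, and adjusted p = 0.750 with an estimated correlation. It did not pass without WT sham replicate 3, OE sham replicates 2 or 3, each WT infarcted replicate, or OE infarcted replicates 1 or 3 (0.0507 to 0.316), nor with lung and thymus terms (median 0.01, 0.864). EMT genes had a median of 0.00 (adjusted p = 0.524) and YAP target genes 0.02 (adjusted p = 0.524), with no member passing.

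The MI effect differed between genotypes for 12 genes, 4 of 28 fibrillar matrix genes among them. Ctsk, a collagen-degrading cathepsin, had MI effects of 1.48 in WT and -0.12 in OE hearts (interaction -1.60, SE 0.19, adjusted p = 0.00410). Postn had 1.95 in WT and 0.13 in OE hearts (interaction -1.81, SE 0.27, adjusted p = 0.0220), and Col3a1 2.21 in WT and 0.16 in OE hearts (interaction -2.05, SE 0.32, adjusted p = 0.0230). Mmp2 had 1.24 in WT and -0.03 in OE hearts (interaction -1.26, SE 0.19, adjusted p = 0.0220). Fbln7, a fibulin of the extracellular matrix, had 1.99 in WT and -0.31 in OE hearts (interaction -2.31, adjusted p = 0.0132). Of the 12 genes, 1 was up and 11 down, with 1416 genes at an unadjusted p below 0.05. DESeq2 on the recovered reads called 153, edgeR 11 and voom 8. In a fit with lung and thymus terms 6 genes passed, among them Ctsk, the only 1 of the 12, and for RA 1 to 12 alone 0, both added after the data were seen. Of the 1008 genes called for MI in WT hearts, 10 passed the interaction, 9 of them up in WT with a lower effect in OE hearts.

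Each matrix call of the interaction named here but Ctsk leaned on single libraries. Postn was lost without WT sham replicates 2 (adjusted p = 0.0699) or 4 (0.0547), OE sham replicates 1 (0.0738), 2 (0.0613) or 3 (0.0604), or WT infarcted replicate 3 (0.0504). Mmp2 was lost without WT sham replicates 2 (0.0557) or 4 (0.0547), OE sham replicates 1 (0.0537) or 3 (0.0604), or OE infarcted replicate 3 (0.0591). Fbln7 was lost without OE sham replicates 1 (0.0537) or 3 (0.0551). Col3a1 was lost without WT sham replicates 1, 2 or 4, OE sham replicates 1, 2 or 3, WT infarcted replicates 3 or 4, or OE infarcted replicate 3 (0.0504 to 0.0738). With lung and thymus terms Ctsk kept its call (-1.78, adjusted p = 0.0203), and Postn (-1.83, 0.0782), Mmp2 (-1.18, 0.0767), Fbln7 (-2.16, 0.0767) and Col3a1 (-1.88, 0.0858) lost it, as did 7 of the 8 eligible genes. The interaction count was 1 without OE sham replicate 1 or 3, 2 without WT sham replicate 2 or 4, 3 without WT infarcted replicate 3 or OE infarcted replicate 3, 4 without OE sham replicate 2, 5 without WT sham replicate 1 or WT infarcted replicate 4, 19 without OE sham replicate 4, 20 without WT sham replicate 3, 21 without OE infarcted replicate 1, 36 without WT infarcted replicate 1 and 53 without WT infarcted replicate 2.

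For panel genes the interaction was -1.82 for Col1a1 (adjusted p = 0.0851), with Ctgf (-1.34, adjusted p = 0.459), Cyr61 (-0.77, adjusted p = 0.670), Ankrd1 (-0.43, adjusted p = 0.814), Vim (-0.44, adjusted p = 0.314), Nppa (-0.39, adjusted p = 0.832), Nppb (-1.48, adjusted p = 0.392), Myh6 (0.03, adjusted p = 0.978), Myh7 (-0.61, adjusted p = 0.699), Acta1 (-0.70, adjusted p = 0.815) and Erbb2 (-0.18, adjusted p = 0.936) not passing. Fibrillar matrix genes counted 0 up, 4 down and 24 not passing (0 up and 25 down adjusted over the list alone), median -1.36, adjusted p = 6.59e-31, and adjusted p = 0.0800 with an estimated correlation. EMT genes counted 0 up, 1 down and 27 not passing (0 up and 12 down adjusted over the list alone), median -0.57, adjusted p = 8.07e-13, and adjusted p = 0.0800 with an estimated correlation. Fibroblast markers counted 0 of 12 passing (0 up and 7 down adjusted over the list alone), median -0.60, adjusted p = 1.16e-09, and adjusted p = 0.0800 with an estimated correlation. Actin and adhesion genes counted 0 of 26 passing (0 up and 2 down adjusted over the list alone), median -0.35, adjusted p = 5.21e-10, and adjusted p = 0.183 with an estimated correlation. Basement membrane genes counted 0 of 14 passing (0 up and 2 down adjusted over the list alone), median -0.25, adjusted p = 9.91e-05, and adjusted p = 0.133 with an estimated correlation. Macrophage markers counted 0 of 16 passing (0 up and 1 down adjusted over the list alone), median -0.69, adjusted p = 4.54e-07, and adjusted p = 0.208 with an estimated correlation. Inflammatory cytokine and chemokine genes counted 0 of 16 passing (0 adjusted over the list alone), median -0.75, adjusted p = 0.000107, and adjusted p = 0.135 with an estimated correlation. YAP target genes counted 0 of 22 passing (0 up and 3 down adjusted over the list alone), median -0.31, adjusted p = 0.00178, and adjusted p = 0.0800 with an estimated correlation. ERK feedback and ETS target genes counted 0 of 21 passing (0 up and 2 down adjusted over the list alone), median -0.40, adjusted p = 0.000107, and adjusted p = 0.158 with an estimated correlation. Fetal and dedifferentiation genes counted 0 of 15 passing (0 adjusted over the list alone), median -0.59, adjusted p = 0.00315, and adjusted p = 0.135 with an estimated correlation.

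Calcium handling and ion channel genes had a positive interaction, with 0 of 24 passing (0 adjusted over the list alone), median 0.25, adjusted p = 0.000178, and adjusted p = 0.208 with an estimated correlation. Fatty acid oxidation genes counted 0 of 25 passing (0 adjusted over the list alone), median 0.18, adjusted p = 0.000646, and adjusted p = 0.667 with an estimated correlation. TCA cycle genes counted 0 of 22 passing (0 adjusted over the list alone), median 0.12, adjusted p = 0.000646, and adjusted p = 0.667 with an estimated correlation. Oxidative phosphorylation genes counted 0 of 29 passing (0 adjusted over the list alone), median 0.07, adjusted p = 0.0245, and adjusted p = 0.807 with an estimated correlation. Fatty acid oxidation and TCA cycle genes were each not called without WT infarcted replicate 4 (adjusted p = 0.0612), nor TCA cycle genes for RA 1 to 12 alone (0.128). Oxidative phosphorylation genes were not called without WT sham replicates 2 or 4, OE sham replicates 1 or 4, WT infarcted replicate 4, or OE infarcted replicates 1 or 4 (0.0604 to 0.642), or for RA 1 to 12 alone (0.491). T and NK cell markers counted 0 of 8 passing (2 up and 0 down adjusted over the list alone), median 1.69, adjusted p = 0.000450, and adjusted p = 0.268 with an estimated correlation. With lung and thymus terms, which cannot test it, this list had a median of 0.26 (adjusted p = 0.846). Immediate-early and heat shock genes counted 0 of 18 passing (0 adjusted over the list alone), median -0.62, adjusted p = 0.00934, and adjusted p = 0.698 with an estimated correlation. This list was not called without OE sham replicate 3 (0.0538), WT infarcted replicate 3 (0.332) or OE infarcted replicate 2 (0.162).

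Matrix genes such as Postn and Col1a1 rose both with overexpression in sham hearts and with MI in WT hearts. Of the 709 genes up with MI in WT hearts, 543 were also up with OE in sham hearts, against 176 for independent calls, and of 299 down calls 248 were also down, against 73.1. These 2 comparisons share the WT sham libraries. Their log2 fold changes correlated at r = 0.492, and simulated data without any effect gave 0.4998 from the shared controls alone. Covariance was 0.182 against 0.0392 in the simulation. When WT sham libraries were divided so that each comparison had its own controls, r was 0.299 to 0.393. That division was tried first with fits of WT libraries alone, which called too few genes to compare. After that was seen, fits over all libraries but the 2 held out replaced them.

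Log2 fold changes of OE correlated between sham and infarcted hearts at r = 0.858 (rank correlation 0.838, slope 0.63), with 1996 genes up in both, against 551 for independent calls, 2169 down in both, against 571, and 1 in opposite directions. The MI effect correlated at r = 0.519 between WT and OE hearts (rank correlation 0.353, slope 0.41). Genes chosen on 1 part of the libraries and measured on the others had a mean MI effect of 0.82 in WT and 0.27 in OE hearts, with a median ratio of 0.348 (0.0566 to 0.759) over the 27 of 36 splits with at least 20 genes. The interaction passed for 12 genes.

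Lung transcripts were present in 5 of 8 infarcted libraries at over 100 normalized reads of Sftpc. Ager, a receptor of lung alveolar cells, stood at 2.69 ± 1.15 in WT sham and 209 ± 195 in WT infarcted hearts (log2 fold change 4.82, SE 1.13, adjusted p = 0.0219). The Ager call was lost without WT sham replicate 2 (adjusted p = 0.0561) or WT infarcted replicates 2 (0.0606), 3 (0.0656) or 4 (0.0576). Lung and thymus terms (0.272) include Ager. Skeletal muscle Myh1 was at 577 and 312 in WT infarcted replicates 1 and 2.

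**Figure D4:**
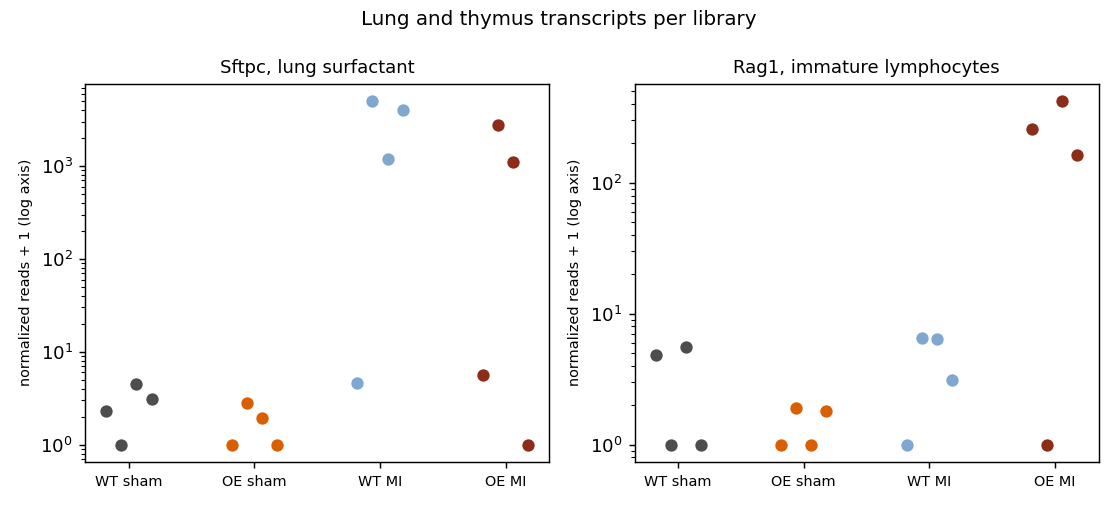
Normalized reads + 1 (logarithmic axes) of Sftpc, a lung surfactant gene, and Rag1, a gene of immature lymphocytes, with 1 point per library and no error bars (n = 4 per group). Sftpc reached 5038 normalized reads in WT infarcted replicate 2.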

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

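The read depth test was set beforehand, those on cardiomyocyte share and size factors only after the breadth of the OE effect was seen. After thinning each library to 11939093 reads, 94.8% of the 7051 calls of OE against WT sham hearts kept their sign and passed, so read depth could account for few of them. A lower cardiomyocyte share alone would lift fibroblast and endothelial markers alike, but their medians differed by 1.06 (standard error 0.44 over list genes, not animals). Fibroblast markers include matrix genes (Col6a1), so a lower share may contribute. On library totals, 84.1% of the 7051 calls kept their sign and passed.

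For MI calls seen in WT and not in OE hearts, the test of spread was set beforehand and the test of genes already shifted in OE sham hearts was chosen only after the result was seen. The ratio of median SD in OE over WT hearts was 0.835 among genes called in WT. It decides nothing, as the model pools SD over groups. Genes up with MI in WT hearts were higher in OE sham hearts than in WT sham libraries not used to pick them for a median of 95.9% of genes over 6 splits of the controls (89.6 to 100%), against 50.7% of all genes. These values are in line with the hypothesis that the genes are already shifted in OE sham hearts, and they do not say why.

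Tests on lung and thymus transcripts in infarcted hearts were all chosen only after these were seen. The bound on the matrix median was set before its value with the terms was known. Sftpb over Sftpc varied 1.23-fold over 5 libraries while Sftpc varied 4.59-fold, as lung tissue beside the heart in the sample could give. Of 8 infarcted libraries, WT replicate 1 and OE replicate 4 had at most 3 reads of Sftpc, unlike expression by the infarcted heart itself. With the terms 109% of the matrix median for MI in WT was left (1.65 and 1.80, median SE 0.238 and 0.309), with 14 matrix genes called. Fewer matrix calls may therefore come with the larger SE. For OE in infarcted hearts some list medians also shrank.

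Tests by regrouping were set before results were seen, except the look at splits that kept the WT groups apart. Only the real 1 of 35 splits called as many genes for OE in sham hearts (7051, highest other 3). The same held for OE in infarcted hearts (4554, highest other 218) and MI in WT hearts (1008, highest other 18). This share is the smallest possible and was not adjusted over 5 comparisons, so chance is less likely but not excluded. For MI in OE hearts chance cannot be excluded: 3 of 35, real count 1, highest other 4. For the interaction the splits do not decide this. Of 100 drawn, 3 called at least the real 12 genes, but exchanging WT labels removes the WT effect itself, which keeps counts low. Only 4 splits, the real one included, kept WT sham and infarcted libraries apart (too few for a share under 0.05), and 3 of these called at least 12 genes. The highest, 1057, exchanged 3 of the 4 OE labels, nearly turning that comparison around.

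Gene list counts were set before results were seen. Exchanging 1 library keeps part of the contrast. Exchanging 2 keeps none, yet reached 18 lists for OE in infarcted and 17 for MI in OE hearts, above the real counts. List p at the preset correlation can be too small. OE in sham hearts had 14 of 35 splits at or above the real 18 lists (highest other 20, or 11 with 2 exchanged). Infarcted hearts had 12 of 35 for 16 lists (highest other 23, or 18). MI in WT had 2 of 35 for 21 lists (highest other 22, or 16). MI in OE had 19 of 35 for 11 lists (highest other 17, or 17). The interaction had 27 of 100 for 16 lists (highest other 22), and 4 of 4 that kept the WT groups apart, too few to decide.

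The outlier test was set before results were seen. Of 184 groups of 4 libraries, 14 had a library set apart, where chance gives about 1 in 20 groups, or 9.20. Libraries below the other 3 of their group, with the gap as a share of the range, were Cyr61 in OE infarcted replicate 2 (0.990), Myh7 in WT sham replicate 4 (0.878), Col1a1 in OE sham replicate 4 (0.887), EMT genes in OE infarcted replicate 2 (0.861), ERBB ligands and receptors in WT infarcted replicate 1 (0.903), sarcomere genes in WT infarcted replicate 4 (0.949), oxidative phosphorylation genes in OE infarcted replicate 3 (0.853), serine synthesis and ATF4 target genes in OE sham replicate 4 (0.931) and endothelial markers in OE sham replicate 3 (0.972). Libraries above the other 3 were ERBB ligands and receptors in WT sham replicate 2 (0.841), basement membrane genes in WT infarcted replicate 4 (0.836), actin cytoskeleton and adhesion genes in WT sham replicate 3 (0.884), Schwann cell markers in OE sham replicate 4 (0.856) and skeletal muscle markers in WT sham replicate 1 (0.848).

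The interaction test was set before results were seen. Its log2 values for the 12 genes that passed were Adamts12 (-1.43), Ankrd63 (1.48), Col3a1 (-2.05), Col5a2 (-1.51), Ctsk (-1.60), Eno2 (-2.90), Fbln7 (-2.31), Mmp2 (-1.26), Pamr1 (-1.75), Postn (-1.81), Ret (-1.08) and Sparc (-1.09). Of these, Adamts12, Ankrd63, Col5a2 and Ret are named because they passed, a choice made after the values were seen. Median log2 values of the 16 lists called were YAP target genes (-0.31), EMT genes (-0.57), ERK feedback and ETS target genes (-0.40), fetal and dedifferentiation genes (-0.59), calcium handling and ion channel genes (0.25), fatty acid oxidation genes (0.18), TCA cycle genes (0.12), oxidative phosphorylation genes (0.0656), fibrillar matrix and fibrosis genes (-1.36), basement membrane genes (-0.25), actin cytoskeleton and adhesion genes (-0.35), inflammatory cytokine and chemokine genes (-0.75), immediate-early and heat shock genes (-0.62), fibroblast markers (-0.60), macrophage markers (-0.69) and T and NK cell markers (1.69).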

How the results depend on the processing

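The interaction, the MI calls and the lists moved most, and the cause was not tested. With an absolute log2 fold change of at least 1, calls were 1895 for OE in sham hearts, 956 for OE in infarcted hearts, 268 for MI in WT and 0 for MI in OE hearts. DESeq2 called 1693, 90 and 153 genes for MI in WT, MI in OE and the interaction, and limma-voom 453 for MI in WT and 2 for MI in OE. An RA number term gave 2 for MI in OE, and only the groups compared 606 and 0 for MI in WT and OE. With replicate number as a replicate block, MI in OE had 0 calls, the interaction 20, and 18 of them inside the WT response, although the numbers do not pair animals. RA numbers 1 to 12 alone, chosen after seeing the data, gave 112, 0 and 0 for MI in WT, MI in OE and the interaction, with adjusted p = 0.491 and a reversed direction for oxidative phosphorylation genes in the interaction. Lung and thymus terms, chosen after seeing the data, gave 1320 for OE in infarcted hearts, 95 and 0 for MI in WT and OE, 6 for the interaction, 3 inside the WT response, and 7 lists for MI in OE. They reversed, for MI in OE, G2/M and cytokinesis (adjusted p = 0.968), sarcomere (0.864), calcium handling and ion channel (0.0265), fatty acid oxidation (0.0177) and TCA cycle genes (0.808), S-phase genes in the interaction (0.0462), and Cd8a for OE in infarcted hearts (log2 fold change -0.0228, adjusted p = 0.992). An estimated correlation left no list called in any comparison. Agreement of the OE effect was r = 0.914 for genes called in either comparison and 0.922 for genes of at least 10 CPM, and that of the MI effect 0.721 and 0.524. Leaving out 1 library gave 6141 to 7152 calls for OE in sham hearts, 3519 to 4954 for OE in infarcted hearts, 276 to 1874 for MI in WT, 0 to 10 for MI in OE, 1 to 53 for the interaction and 1 to 44 inside the WT response. Lists called ranged over 17 to 21, 15 to 18, 19 to 23, 8 to 16 and 13 to 18, and r over 0.812 to 0.867 for OE and 0.400 to 0.563 for MI.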

Other observations

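In OE sham hearts genes of ERBB ligands and receptors moved in both directions. Hbegf, a ligand of the EGF family, rose from 373 ± 31.6 to 2819 ± 565 (log2 fold change 2.89, SE 0.29, adjusted p = 1.15e-06), and Egf fell from 239.7 ± 69.7 to 65.7 ± 25.1 (log2 fold change -1.89, SE 0.36, adjusted p = 0.000436). ERBB ligands and receptors counted 4 up, 3 down and 4 not passing (the same adjusted over the list alone), median -0.12, adjusted p = 0.682, with a mean of 0.46 and an upward test against the negative median. Glycolysis genes counted 9 up, 3 down and 5 not passing (the same adjusted over the list alone), median 0.29, adjusted p = 0.0571. Serine synthesis and ATF4 target genes counted 12 up, 4 down and 7 not passing (13 up and 4 down adjusted over the list alone), median 0.43, adjusted p = 0.0544. Nuclear envelope and LINC complex genes counted 4 up, 6 down and 5 not passing (the same adjusted over the list alone), median -0.14, adjusted p = 0.913, with a mean of 0.05 and a downward test.

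Cell-type lists in OE sham hearts gave no call for the following, with list-alone counts the same unless given. Endothelial markers counted 1 up, 4 down and 9 not passing, median -0.13, adjusted p = 0.436. Mural cell markers counted 3 up, 2 down and 7 not passing, median -0.18, adjusted p = 0.896, with a mean of 0.07 and an upward test. Interferon-stimulated genes counted 5 up, 0 down and 15 not passing (1 up and 0 down adjusted over the list alone), median 0.26, adjusted p = 0.182. Neutrophil markers counted 0 up, 1 down and 8 not passing (0 adjusted over the list alone), median -0.02, adjusted p = 0.996, T and NK cell markers 0 up, 1 down and 7 not passing (0 adjusted over the list alone), median 0.37, adjusted p = 0.926, and B cell markers 1 up, 0 down and 7 not passing (the same adjusted over the list alone), median 0.39, adjusted p = 0.635. Epicardial and mesothelial markers counted 3 up, 2 down and 6 not passing (3 up and 1 down adjusted over the list alone), median -0.66, adjusted p = 0.748. Schwann cell markers counted 1 up, 2 down and 7 not passing, median -0.25, adjusted p = 0.461. Adipocyte markers counted 0 up, 1 down and 9 not passing, median -0.15, adjusted p = 0.886, with a mean of 0.06 and a downward test. Atrial markers counted 1 up, 3 down and 6 not passing, median -0.25, adjusted p = 0.896, with a mean of 0.28 and a downward test. Skeletal muscle markers counted 0 up, 3 down and 7 not passing (0 up and 2 down adjusted over the list alone), median -1.81, adjusted p = 0.0928. Erythroid markers counted 0 up, 2 down and 1 not passing (0 up and 3 down adjusted over the list alone), median -0.98.

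The hypothesis that higher Erbb2 goes with a larger response among the 8 OE hearts was tested only after the result was seen. The correlation of log2 Erbb2 with the response score was r = 0.219 (permutation p = 0.606, adjusted p = 0.940 over 7 relations, none of which passed), with a 95% bound of -0.574 to 0.800. The test was at first written as a p of 0.05 or more, which was met, and was replaced by a bound on r after that was seen, because a missed p does not show absence. A relation may therefore exist or not. Over the 7 relations r ran from -0.542 for fibrillar matrix genes to 0.540 for ERK feedback and ETS target genes. Without OE sham replicate 2 and OE infarcted replicate 1, the 2 libraries lowest in Erbb2 (log2 9.63 each), r was 0.639 for the response score, 0.961 for ERK feedback and ETS target genes, 0.607 for EMT genes (-0.0914 with all 8), 0.505 for YAP target genes (-0.235), 0.477 for oxidative phosphorylation genes (-0.103), -0.0372 for G2/M genes (0.0312) and -0.286 for fibrillar matrix genes, none of them tested.

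The hypothesis that clock phase differs between OE and WT sham hearts was tested only after the result was seen: 3 of 12 clock genes passed, Ciart (-1.44, adjusted p = 0.00259), Nr1d2 (-0.54, adjusted p = 0.00662) and Tef (-0.82, adjusted p = 0.0265). Arntl had a log2 fold change of -0.22 with an SE of 0.71 (adjusted p = 0.817). The test was at first written as fewer than 4 members called, which was met, and the SE of Arntl was added after that was seen, so a difference of phase could be present or absent.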
